A study of Mus musculus with 2 samples.

How the data were processed

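Single nuclei from the brains of C57BL/6 mice were profiled with droplet 3' RNA sequencing (10x Genomics single cell 3' v3, per the labels). Per the labels' protocols and design text, melanoma cells were injected intravenously, and antibody against PD-1 or an isotype control antibody was given intraperitoneally at 250 µg per injection on days 1, 4, 8, 16 and 22. Brains were taken on day 23, and the design text names the cortex as the source of the cells. Nuclei were stained with DAPI and antibodies to NeuN (a neuronal nuclear protein) and Olig2 (a transcription factor of the oligodendrocyte lineage), and nuclei negative for both were collected. There was 1 library per group, and the number of mice behind each library is not given in the sources used here.

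The deposited values were UMI counts per feature and nucleus, in whole numbers. The submitters' processing notes name Cell Ranger 6.1.2 and the mm10 genome, while the comment line of a matrix names Cell Ranger 7.1.0, per the file headers. The annotation, the treatment of intronic reads and the rule that called nuclei are not given in the sources used here. The features were 22630 genes and 1142 families of repetitive elements. Of the gene identifiers, 22513 matched GENCODE vM21 without their version and 22007 matched with it, and 21781 features were protein coding there. A second copy of each file held the same values in 6 of 6 file pairs, so 1 copy was used. Of 569 genes in the fixed lists, 560 were among the features, and Clec7a, Kcnq1ot1, Malat1, Meg3, Mx1, Mx2, Neat1, Tsix and Xist were not analysed here. Repeat families name no gene and were kept out of class sums. They held 9.92% of UMIs in the anti-PD1 library and 7.81% in the isotype library. Genes of families with near-identical members (H2, Ifi, Oas, Fcgr, Dynlt1) are uncertain where reads could be split between members, and the strand and multi-mapping rules of the counting are not given in the sources used here.

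Nuclei with at least 200 features and at most 5% mitochondrial UMIs were kept. No nucleus fell under 200 features, and 2 anti-PD1 nuclei exceeded the mitochondrial limit. Doublets were called per library with Scrublet as implemented in scanpy 1.11.5 and removed. It called 2 nuclei in the anti-PD1 library and 0 in the isotype library, far below the rate of 6% it was set to expect. The true rate is not known, but doublets are taken to have largely remained. These steps left 7876 and 5887 nuclei. Counts per 10000 were log transformed, 2000 variable genes and 30 principal components were taken for both libraries jointly, and a graph of 15 neighbours was clustered with the Leiden method (leidenalg 0.10.2, igraph 0.11.9) at resolution 1. Clusters were named from 18 marker sets chosen before the data were examined. A marker counted as raised at 2-fold the median of the other clusters, after adding 10 CPM. A name needed at least 3 raised markers, a share of raised markers of at least 0.333, and no other class with more markers among the 10 leading genes. These limits were set after the clusters had been seen, as were 6 lists of genes of brain regions used in the closing observations. They left clusters unnamed that held 3.10% of anti-PD1 and 4.77% of isotype nuclei. Cell type names below mean nuclei that resemble that type by these markers.

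UMI counts were summed over the nuclei of a class in each library and scaled to CPM, the count relative to the class sum over genes. The ratio of anti-PD1 to isotype was taken on the log2 scale with a prior count of 0.5. Classes with at least 50 nuclei in each library were compared. Intervals are exact 95% intervals (Clopper-Pearson for shares, Poisson for sums, conditional binomial for ratios). The interval of a list's median came from 1000 Poisson redraws of its members' counts. All intervals cover counting error only. With 1 library per group no test across animals was possible, and no p-value is given. The values compare these 2 libraries, not the treatments.

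Of 29 fixed lists, a list's median was taken over members with at least 20 UMIs in the class, and its percentile among 10000 random lists of the same size, matched on expression in 20 bins, describes these libraries. Genes were named by a rule chosen before the data were examined. Genes with at least 50 UMIs in a class were ranked by the interval bound nearest 0, and the 12 highest and 12 lowest were taken in microglia and the 4 highest and 4 lowest in each other class. Predicted genes without a name, mitochondrial, ribosomal protein and haemoglobin genes were left out. So were genes whose CPM, multiplied by 4, stayed below that of their highest class in the same library. A gene that this rule ranked among those of inhibitory neurons is not reported here. Classes of very few nuclei counted as highest classes, which removed many low genes. List members named as examples had the most UMIs or the largest ratio with an interval excluding 0, or were chosen after their values were seen. For shares of nuclei with a UMI, microglia were thinned to 642 gene UMIs each. That depth was the lowest quartile of microglia in the library where this quartile was lower.

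The ratio and list calculations were tested on simulated microglia sums with 200 changed genes among 11014. An interval that excluded 0 in the right direction was found for 98% of 50 genes at a fold of 2 and 94% at a fold of 0.5, and for 56% and 50% at folds of 0.8 and 1.2. Among unchanged genes the interval covered 0 for 95.7%. For 200 simulated lists of 20 genes at a fold of 1.2, the interval of the median covered the true value in 99%. Counts were drawn from the Poisson model that the intervals assume, with the same fold for every list member. The simulation thus checks the calculation, not how the intervals do on real lists of mixed members. Alternatives covered the filters on nuclei, doublets, resolution, clustering of each library alone, naming per nucleus, scaling by the trimmed mean of M values, minimum UMIs, prior counts, thinning and denominators. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures matplotlib 3.10.9. Gene positions are from GENCODE vM21 on GRCm38, the assembly called mm10.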

Results

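Nuclei from the brains of melanoma-bearing mice given anti-PD1 antibody, which blocks the inhibitory receptor PD-1, were compared with nuclei from mice given an isotype control antibody. Each group had 1 library. The anti-PD1 library held 7880 nuclei and 12479167 UMIs, with a median of 1298 UMIs per nucleus. The isotype library held 5887 nuclei and 8047334 UMIs, with a median of 1182. Mitochondrial UMIs made up 0.0330% and 0.0309%. Without replicates, every difference below has no replicate check, and intervals are 95% intervals for counting error.

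The first question was which cells the sort had enriched and in what proportions. Microglia, the resident macrophages of brain tissue, were the most frequent class in both libraries, with 69.0% of anti-PD1 nuclei (68.0% to 70.0%; 5436 of 7876) and 66.0% of isotype nuclei (64.7% to 67.2%; 3884 of 5887). Border macrophages, which line vessels and meninges, made up 3.33% (2.94% to 3.75%) and 2.92% (2.51% to 3.38%). Astrocytes made up 5.21% (4.73% to 5.72%) in anti-PD1 and 8.24% (7.55% to 8.97%) in isotype. Fibroblasts made up 3.42% and 2.87%, mural cells 1.21% and 0.459%, and endothelial cells 0.305% and 0.0679%. Classes that a sort against NeuN and Olig2 should deplete were still present. Inhibitory neurons made up 10.4% and 9.46%, excitatory neurons 0.609% and 2.07%, and oligodendrocytes 3.45% and 3.16%. The sort can set all of these shares. When each nucleus was named from its own marker sets in place of its cluster, the order of the libraries for microglia turned, with 74.9% in anti-PD1 and 78.6% in isotype. Without the highest 6% of doublet scores in each library they were 69.7% and 68.9%, a smaller difference.

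**Figure D1:**
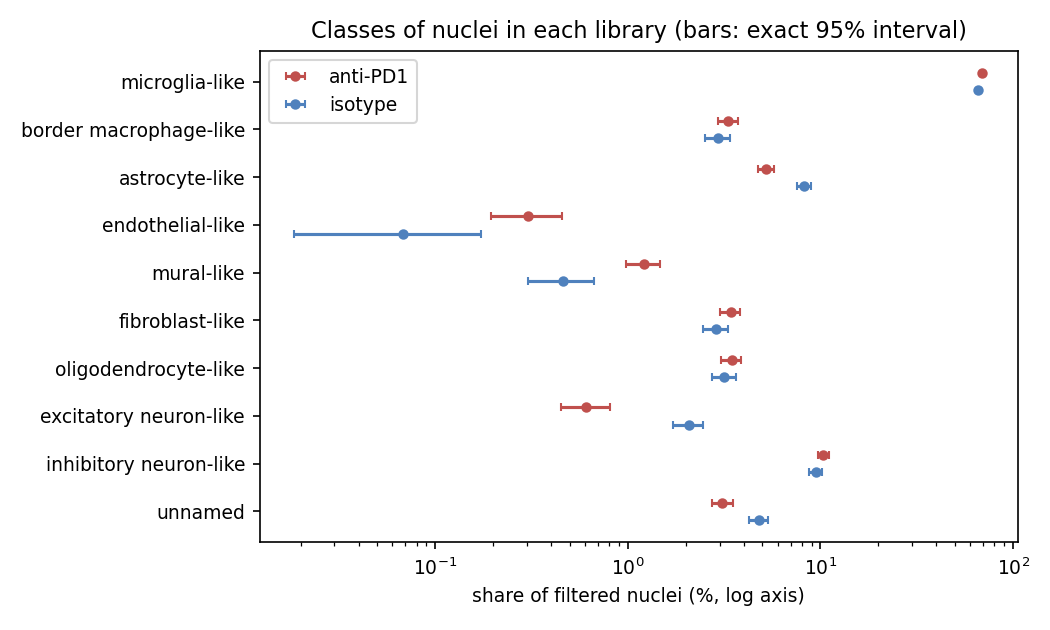
Share of filtered nuclei (percent, log axis) in each class named from markers, for the anti-PD1 and isotype libraries, with exact 95% intervals for counting error as bars. Microglia-like nuclei were the largest class in both, at 69.0% and 66.0%.

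No cluster was named for T or NK cells, monocytes or dendritic cells, B cells, neutrophils, oligodendrocyte precursors or melanoma cells. The unnamed cluster 19 was led by leukocyte genes such as Ebf1, Cd74, S100a9 and Ikzf3. It held 62 anti-PD1 and 35 isotype nuclei, or 0.787% and 0.595%. In it 6 of 8 B cell markers were raised. It stayed unnamed because another class had 2 markers among its leading genes, against 1 B cell marker. Nuclei with UMIs of at least 3 T or NK cell markers numbered 5 of 7876 in anti-PD1 and 4 of 5887 in isotype, or 0.0635% (0.0206% to 0.148%) and 0.0679% (0.0185% to 0.174%). For neutrophil markers these numbers were 3 and 9, for monocyte or dendritic cell markers 2 and 2, and for B cell markers 26 and 12. Oligodendrocyte precursor markers gave 23 and 8 nuclei, erythroid markers 24 and 15, and ependymal markers 1 and 0. Choroid plexus and melanoma markers gave 0 nuclei in each library. The floor of 3 nuclei is 0.0381% in anti-PD1 and 0.0510% in isotype, and the exact upper bounds are 0.0468% and 0.0626%. These limit the share of nuclei with UMIs of 3 such markers, not that of such cells.

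Different clusters held most microglia of the 2 libraries. Clusters 0 and 2 held 37.1% and 25.5% of anti-PD1 microglia against 17.2% and 13.3% of isotype microglia. Clusters 1 and 3 held 16.7% and 12.3% of anti-PD1 microglia against 34.9% and 23.8% in isotype. Cluster 5 was led by interferon-induced genes such as Nlrc5, Ifi204, Oasl2 and Usp18, and cluster 11 by the pituitary hormone genes Gh and Prl. Cluster 5 held 7.32% of anti-PD1 and 5.38% of isotype microglia, and cluster 11 held 1.03% and 5.43%. Since these genes define the clusters, such shares and the ratios of the genes are not separate results.

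The second question was which gene programmes differed in microglia between the antibody groups. Genes of phagocytosis and the lysosome, the complement system, antigen presentation on MHC class I, the type I interferon response and the disease-associated microglial state were higher in the anti-PD1 library, by median ratios between 0.28 and 0.37 on the log2 scale. Myelin genes (0.32) and mitochondrially encoded genes (0.27) were higher by similar amounts, while synapse and astrocyte homeostasis genes were at 0.03. MHC class II, interferon gamma, Syk and Toll-like receptor lists had medians near 0. That of MHC class II depended on the setting, at 0.42 thinned and 0.48 over members with at least 100 UMIs. The median over all genes with at least 100 UMIs was 0.00. Counts of higher members below give the sign of each ratio alone, and many members had intervals that include 0. The sums behind these values were 6693357 gene UMIs in anti-PD1 and 4538439 in isotype.

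The phagocytosis and lysosome list had a median log2 ratio of 0.37 (0.29 to 0.40), with 17 of 22 members higher and a percentile of 100 among random lists. The lysosomal proteases Ctsl, Ctsz and Ctsb had ratios of 0.70 (0.60 to 0.81), 0.59 (0.50 to 0.68) and 0.46 (0.37 to 0.55), and Cd68, a lysosomal membrane protein of phagocytes, 0.65 (0.54 to 0.77). Mertk, a receptor for apoptotic cells, went the other way, at -0.25 (-0.29 to -0.21). The complement list had a median of 0.29 (0.13 to 0.46), with 9 of 9 members higher (percentile 99.99). C1qa, C1qb and C1qc, which encode the chains of the recognition molecule C1q, stood at 2337, 2026 and 2352 CPM in anti-PD1 and 1620, 1415 and 1653 CPM in isotype, with ratios of 0.53, 0.52 and 0.51. The disease-associated list had a median of 0.29 (0.22 to 0.52), with 15 of 19 members higher (percentile 99.99), among them Cd9 at 0.56 (0.46 to 0.66) and Trem2, a lipid-sensing receptor, at 0.25 (0.17 to 0.33). Apoe was at -0.06 (-0.14 to 0.02).

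The MHC class I list had a median of 0.36 (0.21 to 0.45), with 14 of 15 members higher (percentile 100). H2-D1, a heavy chain gene, had 1381 UMIs in anti-PD1 and 502 in isotype, a ratio of 0.90 (0.75 to 1.05). H2-T23 was at 0.89 (0.63 to 1.16), H2-K1 at 0.36 (0.21 to 0.52) and B2m, the light chain, at 0.25 (0.12 to 0.38). The list median was 0.22 with the gene length trend removed and 0.20 over members near their highest class. The type I interferon list had a median of 0.28 (0.21 to 0.49), with 22 of 22 members higher (percentile 99.96). Ifi207, Ifi204 and Oasl2 had ratios of 1.96 (0.99 to 3.23), 1.41 (0.85 to 2.05) and 1.28 (0.75 to 1.88). Over members near their highest class the list median was 0.19. Within clusters 0, 1 and 2 it was 0.05, 0.03 and 0.10, with intervals that include 0, and within clusters 3 and 5 it was 0.38 and 0.12. These medians were over the 12, 10, 10, 9 and 19 members with at least 20 UMIs in the cluster, not over all 22. The interferon gamma list had a median of -0.01 (-0.13 to 0.09), with 5 of 13 members higher (percentile 39.7).

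The MHC class II list had a median of 0.02 (-0.16 to 0.38), with 5 of 9 members higher (percentile 47.7). H2-DMb1 was at 0.79 (0.55 to 1.03) and Cd74, the invariant chain, at -0.07 (-0.50 to 0.38). This median depended on low members, was 0.48 over members with at least 100 UMIs, and ran from -0.093 to 0.48 over the settings tried. The homeostatic list had a median of 0.11 (0.05 to 0.13), with 11 of 18 members higher (percentile 99.93). Cst3 was at 0.31 (0.29 to 0.33) and P2ry12 at 0.21 (0.17 to 0.25). Removing the gene length trend lowered the median of this list to 0.037. The Syk and ITAM list had a median of 0.02 (-0.03 to 0.10), with 11 of 21 members higher (percentile 84.3). Inpp5d and Blnk were at -0.25 (-0.28 to -0.21) and -0.26 (-0.34 to -0.18), and the Fc receptor chain gene Fcer1g at 0.37 (0.28 to 0.45). The Toll-like receptor and TAK1 list had a median of -0.03 (-0.09 to 0.05; percentile 31.7), with Cd14 at 0.51 (0.33 to 0.68). The NF-kB list had a median of 0.10 (0.04 to 0.24; percentile 92.0), with Tnf at 0.92 (0.36 to 1.55) and Ccl3 at 0.77 (0.22 to 1.37).

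**Figure D2:**
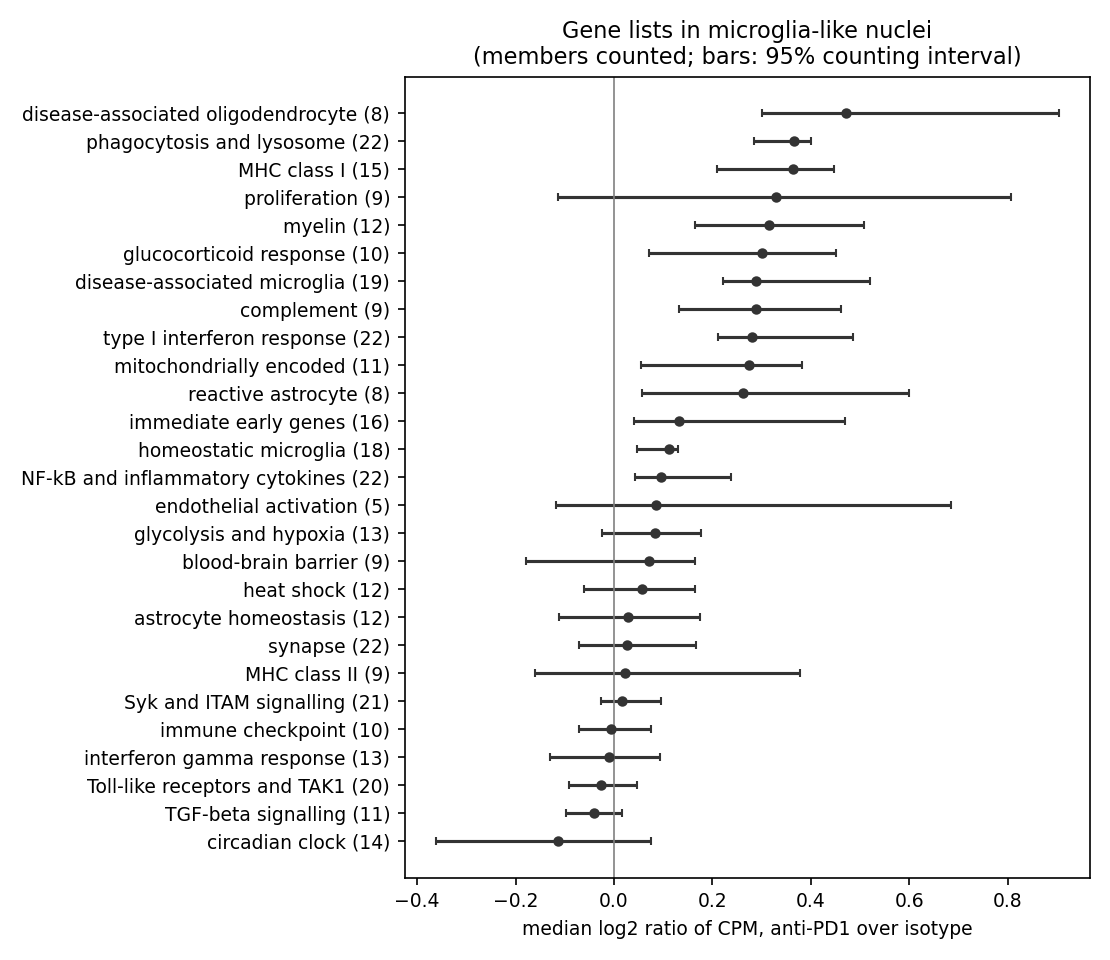
Median log2 ratio of CPM (anti-PD1 over isotype) of each fixed gene list with at least 3 members measured in microglia-like nuclei, with 95% counting intervals as bars and the number of members in brackets. The phagocytosis and lysosome list lies at 0.37 and the Syk and ITAM list at 0.02.

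Other lists in microglia were as follows. The glucocorticoid list had a median of 0.30 (0.07 to 0.45; percentile 99.5), with Sgk1 at 0.65 (0.49 to 0.81). Immediate early genes had a median of 0.13 (0.04 to 0.47; percentile 84.4), with Junb at 0.55 (0.38 to 0.71) and Btg2 at -0.41 (-0.59 to -0.22). With the gene length trend removed, the medians were 0.024 for immediate early, 0.13 for mitochondrially encoded and -0.033 for heat shock genes. The circadian list had a median of -0.11 (-0.36 to 0.07; percentile 5.41), and its members went both ways, with Tef at -0.72 (-0.92 to -0.51) and Bhlhe41 at 0.60 (0.47 to 0.72). The immune checkpoint list had a median of -0.01 (-0.07 to 0.07), with Lag3 at 0.64 (0.40 to 0.90). Medians were 0.06 for heat shock, 0.33 (-0.11 to 0.81) for proliferation, -0.04 for TGF-beta signalling, and 0.08 for glycolysis and hypoxia. Some lists of other cell types and of RNA quality were higher too. Myelin genes had a median of 0.32 (0.16 to 0.51) and mitochondrially encoded genes 0.27 (0.06 to 0.38). Reactive astrocyte genes had a median of 0.26 (0.06 to 0.60), disease-associated oligodendrocyte genes 0.47 (0.30 to 0.90), which share H2-D1, H2-K1 and B2m with the MHC class I list, and astrocyte homeostasis genes 0.03. Medians were 0.03 for synapse, 0.09 for endothelial activation and 0.07 for blood-brain barrier genes. Snhg11, the measured member of the nuclear-retained list, was at 0.38, and Ddx3y, that of the sex-linked list, at -0.11. Short genes had higher ratios than long ones. Among 10 bins of gene length, the median was 0.14 in the shortest and -0.06 in the longest, with a Spearman correlation of -0.26 across 9625 genes, which are not independent replicates.

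Among single genes ranked in microglia, the highest were Pcp2 (258 UMIs in anti-PD1 and 1 in isotype; log2 ratio 6.87, 4.96 to 12.8) and Car8 (201 and 7; 4.19), which are abundant in Purkinje cells of the cerebellum, and Pvalb (348 and 47; 2.31). Pcp2 was at 38.5 CPM in anti-PD1 microglia and at a median of 37.2 CPM in the other classes of that library. The list went on with Mid1 (1.49), Ddit4 (1.35), Ces4a (1.71), Sdf2l1 (1.17), Tacc2 (1.22), Dynlt1a (1.02) and Dalrd3 (0.85). In the other classes, median CPM was also higher in anti-PD1 than in isotype for each of these genes. It was 80.0 and 37.1 for Mid1, 39.9 and 14.1 for Ddit4, 12.7 and 4.29 for Ces4a, and 29.5 and 10.9 for Sdf2l1. It was 60.5 and 46.9 for Tacc2, 69.0 and 58.5 for Dynlt1a, and 285 and 164 for Dalrd3. These differences were thus not confined to microglia. Cd81, a tetraspanin on chromosome 7 (143052739 to 143067934), had 860 CPM in anti-PD1 and 513 in isotype, a ratio of 0.74 (0.67 to 0.81). The other classes had medians of 605 and 315 CPM, a difference in the same direction. Olfml3, a secreted protein of microglia on chromosome 3 (103722222 to 103738001), had 547 and 328 CPM, a ratio of 0.74 (0.65 to 0.83). Its medians in the other classes were 78.5 and 95.8 CPM, the opposite direction. The lowest of the ranked genes was Prl, the pituitary hormone prolactin (20 and 160 UMIs; -3.53, -4.31 to -2.89), with a median of 46.8 CPM in the other isotype classes. Gh was lower still (8 and 303 UMIs; -5.72, -7.03 to -4.81), but the limit against the highest class kept it out of the ranking. The neutrophil gene S100a9 was at -1.70 (-2.31 to -1.13) and the neuropeptide genes Tac1 and Penk at -1.08 and -0.70. Also low were Amacr (-1.32), Eps8l1 (-0.82), Lst1 (-0.68, -0.84 to -0.52), Tef (-0.72), Zfp72 (-1.12), Klhl3 (-0.74), Fam83g (-1.11) and Akr1b3 (-0.72).

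**Figure D3:**
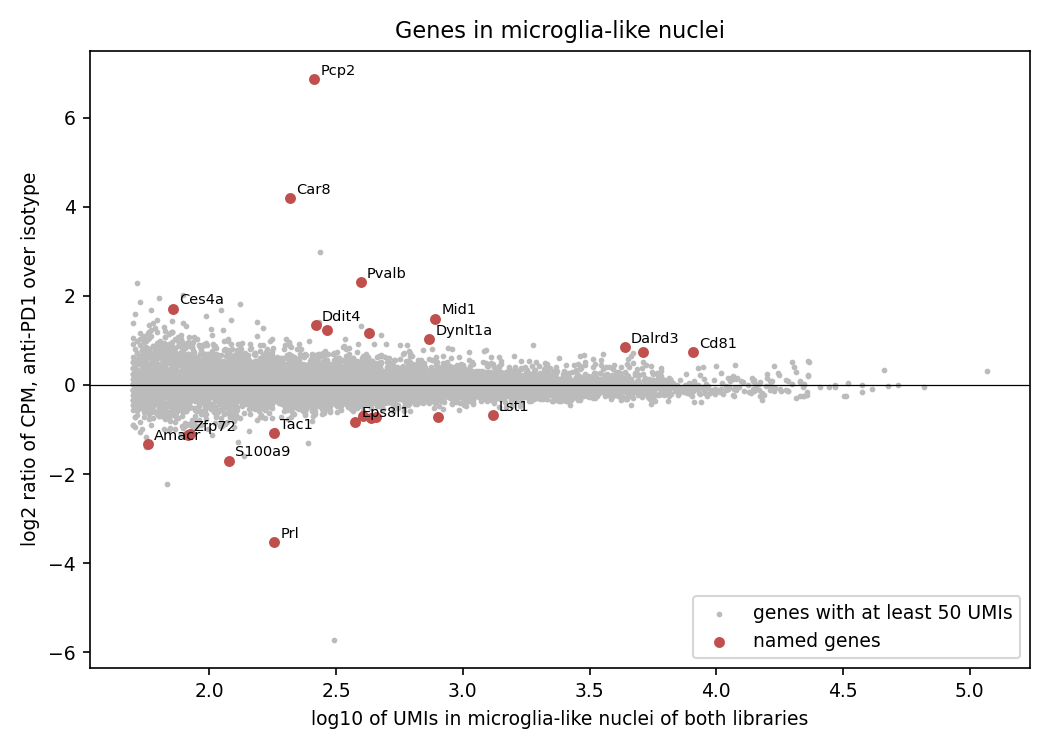
Log2 ratio of CPM (anti-PD1 over isotype) in microglia-like nuclei against log10 of the UMIs of both libraries, for genes with at least 50 UMIs, with the ranked genes in red and those with room labelled. Pcp2 lies highest of the ranked genes at 6.87 and Prl lowest at -3.53.

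The third question was in how many microglia these genes were seen at equal depth. At 642 UMIs per nucleus, which left out 882 anti-PD1 and 969 isotype microglia and 24 and 145 astrocytes, 44.6% of anti-PD1 and 38.2% of isotype microglia had a UMI of any MHC class I gene (unthinned 62.2% and 53.8%). H2-D1 was seen in 12.1% and 7.31%. Astrocytes at that depth, as background, had an MHC class I UMI in 18.1% and 18.5%, with median depths before thinning of 1649 and 948 UMIs, against 1072.5 and 1123.5 in microglia. Any MHC class II gene was seen in 13.5% and 10.6% of microglia (unthinned 22.4% and 18.3%) and in 4.15% and 3.82% of astrocytes. Any checkpoint gene was seen in 75.7% and 77.8% of microglia (unthinned 86.2% and 86.5%) and 29.0% and 34.1% of astrocytes. Any Syk list gene was seen in 99.0% and 99.2% of microglia (unthinned 99.4% and 99.2%), and Syk itself in 12.9% and 13.2%. In astrocytes a Syk list gene was seen in 31.3% and 40.3%.

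The gene of the antibody's target, Pdcd1, was near the limit of detection. It had 17 UMIs over all anti-PD1 nuclei and 6 over all isotype nuclei, of which 14 and 4 were in microglia. Cd274, which encodes the ligand PD-L1, had 130 and 77 UMIs in microglia, or 19.4 and 17.0 CPM, and 13 and 1 in border macrophages. Over all nuclei it went the other way, with 181 and 143 UMIs, or 16.1 and 19.3 CPM. Some of these UMIs lay in unnamed clusters, more of them in isotype than in anti-PD1, so this reversal need not hold within classes. The counting intervals of the libraries overlapped in microglia and over all nuclei. Pdcd1lg2 had 3 and 3 UMIs over all nuclei. Melanocyte genes were scarce, with Mlana at 1 and 1, Pmel at 21 and 12, Tyr at 19 and 9, Tyrp1 at 1 and 3, Dct at 2 and 2, Oca2 at 28 and 21 and Slc45a2 at 2 and 0 UMIs over all nuclei. Mitf, which is also expressed in macrophages, had 3242 and 2642 UMIs, of which 2395 and 2010 were in microglia.

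The fourth question was whether other classes differed in the same lists. In border macrophages (262 and 172 nuclei), complement genes had a median log2 ratio of 0.52 (0.32 to 0.66), with 10 of 10 members higher, disease-associated genes 0.49 (0.31 to 0.76) and phagocytosis and lysosome genes 0.40 (0.21 to 0.55). Mitochondrially encoded genes were higher too, at 0.75 (0.13 to 1.30), with 4 of 4 members higher, or 0.52 with the gene length trend removed. Apoe was at 0.79 (0.69 to 0.90). TGF-beta signalling genes had a median of -0.54 (-0.64 to -0.19), with Tgfbr1 at -0.85 (-1.11 to -0.60), and type I interferon genes -0.28 (-0.44 to 0.05). Clec4n (1.97, 1.07 to 3.15), Lipa (1.87), Apoe and the scavenger receptor gene Cd36 (1.39) ranked highest, and Upp2 (-1.75), Arl8b (-1.56), Wwox (-1.05) and Chn2 (-1.31) lowest.

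In fibroblasts (269 and 169 nuclei, most in cluster 12 for anti-PD1 and cluster 15 for isotype), type I interferon genes had a median of -0.72 (-1.09 to -0.29), with 11 of 11 members lower. Oasl2 was at -1.76 (-2.56 to -1.02) and Rnf213 at -1.10 (-1.74 to -0.46). Mitochondrially encoded genes had a median of -1.43 (-1.82 to -1.04) and disease-associated genes 0.53 (0.27 to 0.87). Spp1, which encodes osteopontin (2.19, 1.51 to 3.01), Prg4 (2.07), Apod (1.43) and Col15a1 (2.08) ranked highest, and Fam227b (-3.71), Adamtsl3 (-1.78), Clic4 (-1.73) and Rtl4 (-1.74) lowest. In oligodendrocytes (272 and 186 nuclei), myelin genes had a median of 0.01 (-0.11 to 0.14). The protease gene Klk6 (1.39, 1.02 to 1.78), Spry2 (1.78), Errfi1 (1.27) and Zcchc9 (1.57) ranked highest, and Opalin, a myelin membrane protein (-2.34, -3.27 to -1.53), Pakap (-1.67), Rcan2 (-1.14) and Tspyl4 (-1.34) lowest.

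Astrocytes (410 and 485 nuclei) and inhibitory neurons (816 and 557) were made of different clusters in the 2 libraries. The trimmed mean of M values shifted ratios by -0.11 in astrocytes and -0.13 in inhibitory neurons, the level that genes in these classes are to be read against. Cluster 14 held 192 anti-PD1 astrocytes and 1 isotype astrocyte, and cluster 13 held 185 and 10 inhibitory neurons. Astrocytes ranked highest in Gria4 (5.66, 5.38 to 5.97), Abi3bp (6.04), Mybpc1 (5.75) and A2m (6.02). They ranked lowest in Prl, Crym (-3.07), Gabbr2 (-2.28) and P3h2 (-2.40). Prl had 0 and 98 UMIs, a ratio of 0.0298 with the floor of 3 UMIs in place of 0. The upper bound of its exact interval was -4.74 on the log2 scale. Inhibitory neurons ranked highest in Cnpy1 (3.70), Cntn4 (3.21, 2.94 to 3.51) and Cntn6 (3.95) and lowest in Slit1 (-2.41), Ptk2b (-2.37), Mex3a (-2.40) and Slc7a7 (-2.04). Without cluster 14, Gria4 was at 1.38 and A2m at 3.28, while Abi3bp had 6 and 2 UMIs left and Mybpc1 0 and 1, under the limit of 20. Crym was then at -2.14, Gabbr2 at -1.61 and P3h2 at -1.95. Without cluster 13, Cntn4 was at -0.011, while Cnpy1 had 4 and 1 UMIs left and Cntn6 6 and 4. Homeostatic microglial genes were lower in anti-PD1 astrocytes, with a median of -1.02 (-1.21 to -0.79), and in inhibitory neurons, at -1.13 (-1.21 to -0.91). The astrocyte median was -0.27 over the 5 members near their highest class and -0.71 without cluster 14. Median depth in these classes also differed, over all features, at 1845 and 1036 UMIs in astrocytes and 1859 and 1011 in inhibitory neurons. Whether RNA from microglia in these nuclei set the homeostatic medians was not tested. Synapse genes in inhibitory neurons had a median of 0.47 (0.40 to 0.67), and astrocyte homeostasis genes in astrocytes 0.40 (0.28 to 0.60). Mitochondrially encoded genes in astrocytes had a median of 0.54 (0.17 to 0.85), or 0.25 with the gene length trend removed.

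**Figure D4:**
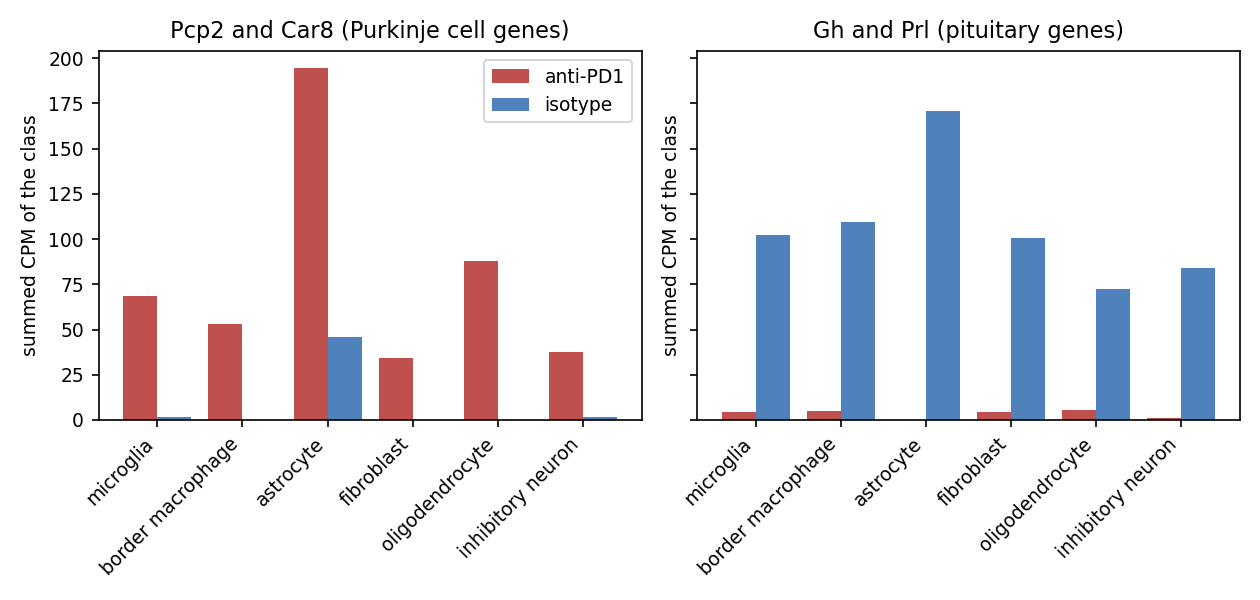
Summed CPM of Pcp2 and Car8 (left) and of Gh and Prl (right) in each compared class of the anti-PD1 and isotype libraries, as bars from 0. Pcp2 and Car8 were higher in every plotted class of the anti-PD1 library, and Gh and Prl in every plotted class of the isotype library.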

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

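All tests of explanations given here were chosen after the results they bear on had been seen, at least in part. Repeat families, which comparisons left out except in 1 alternative, took 9.92% of UMIs in the anti-PD1 library against 7.81% in the control library. The ratio was 1.25 in microglia and 1.35 in fibroblasts.

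Several lists had medians of opposite direction in microglia and in another class, with counting intervals excluding 0 on each side, and these differences were not tested. In fibroblasts the type I interferon list was at -0.72 against 0.28 in microglia, and mitochondrially encoded genes at -1.43 against 0.27. In border macrophages the NF-kB list was at -0.31 against 0.10. Oligodendrocytes had -0.42 for homeostatic microglial genes and -0.78 for mitochondrially encoded genes. Of the 16 homeostatic members measured there, 2 were near their highest class, with a median of -0.36. Median depth of oligodendrocytes, over all features, was 1988.5 UMIs in anti-PD1 and 1030.5 in isotype. RNA from microglia in these nuclei was not tested. Astrocytes had -1.02 for homeostatic, -0.39 for NF-kB, -0.31 for complement and -0.18 for phagocytosis and lysosome genes, but -0.27 for homeostatic genes over members near their highest class and -0.11 for NF-kB genes without cluster 14. Inhibitory neurons had -1.13 for homeostatic, -0.51 for disease-associated, -0.49 for MHC class I and -0.92 for NF-kB genes. They had -0.89 for complement, -0.80 for phagocytosis and lysosome, -0.58 for reactive astrocyte and -0.37 for mitochondrially encoded genes. Syk and checkpoint genes were lower there too, at -1.29 and -1.08, and median depth was 1859 and 1011 UMIs over all features. RNA from microglia in astrocytes and inhibitory neurons was not tested either, so these medians cannot be read as separate results. Against the class shifts of -0.11 and -0.13, the intervals for astrocyte phagocytosis and lysosome genes and for MHC class I, reactive astrocyte and mitochondrially encoded genes of inhibitory neurons include no difference. Over members near their highest class, mitochondrially encoded genes were at 0.12 in oligodendrocytes and 0.18 in inhibitory neurons (1 member each), and reactive astrocyte genes at -0.07 in inhibitory neurons (3 members).

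The phagocytosis and lysosome list was higher in anti-PD1 microglia by a median of 0.37. With the gene length trend removed it was still 0.32 (0.27 to 0.37), which argues against that trend as the whole cause. The median ratio in the shortest bin of gene length was 0.14, so the size of the trend had largely settled this outcome. With cluster proportions of anti-PD1 set to those of isotype it was 0.26 (0.22 to 0.33), which argues against cluster proportions as the whole cause. Border macrophage markers in microglia had a median of 0.14 (-0.34 to 0.52), too wide an interval to exclude RNA from those cells. A treatment effect, differences between mice and the brain region sampled stay open and untested, as 1 library per group confounds them.

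The type I interferon list was higher in anti-PD1 microglia by 0.28, and by 0.28 (0.21 to 0.43) with the length trend removed, which argues against that trend as the whole cause. Here too the size of the trend, at 0.14 in the shortest bin, had largely settled the outcome. With equal cluster proportions the median was 0.19 (0.10 to 0.33), which argues against those proportions as the whole cause. Within clusters 0, 1 and 2 it was 0.05 (-0.03 to 0.30), 0.03 (-0.10 to 0.20) and 0.10 (-0.18 to 0.39), intervals that include 0. In clusters 3 and 5 it was 0.38 (0.04 to 0.57) and 0.12 (0.01 to 0.45). These medians were over 12, 10, 10, 9 and 19 members, against 22 for the whole class, so they do not compare the same genes. Proportions may still carry part of the difference. RNA from border macrophages stays open, with the same marker median of 0.14, as do treatment, mice and region.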

How the results depend on the processing

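No paired analysis was possible because each group had 1 library, and none could be left out. Alternatives chosen after seeing the data were the doublet score limit, the length trend, repeat features and the left-out clusters, and for classes other than microglia the limit against the highest class. Leaving out microglia clusters led by another class gave no value, as none was so led. Among medians of the immune lists in the compared classes, 361 values stayed within their counting interval and 12 did not. Of the 361, 57 came from keeping doublets, which added back 2 nuclei. The trimmed mean of M values shifted microglia by 0.0098. Such settings changed little, so these counts do not measure robustness. Over 17 settings the microglial median ran from 0.32 to 0.40 for phagocytosis and lysosome, 0.26 to 0.46 for disease-associated, 0.22 to 0.39 for complement and 0.19 to 0.38 for type I interferon genes. It ran from 0.20 to 0.39 for MHC class I, 0.066 to 0.20 for NF-kB and 0.037 to 0.12 for homeostatic genes. Toll-like receptor genes ran from -0.070 to -0.023. MHC class II (-0.093 to 0.48), Syk (-0.014 to 0.036) and interferon gamma genes (-0.052 to 0.028) turned sign. The cause was not tested unless stated.

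Microglia were 74.9% of anti-PD1 and 78.6% of isotype nuclei when named per nucleus, and 80.7% and 77.3% without neurons and oligodendrocytes, by construction. Without the highest 6% of doublet scores they were 69.7% of anti-PD1 and 68.9% of isotype nuclei, so the libraries nearly met. The MHC class II median was 0.48 with at least 100 UMIs, 0.42 thinned, and 0.48 over members near their highest class. Over such members MHC class I was 0.20 and type I interferon 0.19, and averaging over nuclei gave 0.21 for the latter. Without the length trend, the homeostatic median was 0.037 and astrocyte complement -0.59. Over members near their highest class, astrocytes had -0.27 for homeostatic and -0.68 for Syk genes, and without cluster 14 -0.71 for homeostatic and -0.11 for NF-kB genes. Without cluster 14, Gria4 was at 1.38 and A2m at 3.28. Without cluster 13, Cntn4 turned to -0.011, since that cluster held most of its RNA in inhibitory neurons.

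Fewer UMIs lower shares by construction. At 321 UMIs, shares in anti-PD1 and isotype were 6.82% and 6.33% for MHC class II, 27.5% and 22.7% for MHC class I, 51.0% and 53.8% for checkpoint, and 90.2% and 91.2% for Syk genes. Unthinned, they were 22.4% and 18.3%, 62.2% and 53.8%, 86.2% and 86.5%, and 99.4% for Syk in anti-PD1. Depth limits what can be said of Pdcd1, Pdcd1lg2, T cell and melanoma genes.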

Other observations

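All tests given here were chosen after the results they bear on had been seen, and the region lists were written after the values of many of their genes had been seen. Purkinje cell genes were higher in the anti-PD1 library over all nuclei, with 10 of 10 measured list members higher and a median log2 ratio of 1.09 (0.847 to 1.504). Pcp2 had 457 and 4 UMIs. The 2 members whose values had not been seen, Dner and Pcp4, had a median of 0.18 (0.06 to 0.29). Granule cell genes had a median of 1.89 (1.45 to 2.34) and Bergmann glia genes 3.15 (2.49 to 3.92). The 3 measured pituitary genes had a median of -4.05 (-4.68 to -3.62), with Gh at 10 and 1012 UMIs and Prl at 32 and 355, while Pomc went the other way, at 61 and 27 (0.56, -0.10 to 1.29). Forebrain genes were at -0.45 (-0.78 to -0.12), with 3 of 10 members higher, and the 6 members not seen before at -0.34 (-0.87 to 0.01), an interval that includes 0. Ttr, a choroid plexus gene, had 455 and 45 UMIs, while the median of 3 measured choroid plexus genes was -0.16 (-0.60 to 1.06).

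A candidate explanation is that more cerebellar tissue entered the anti-PD1 library, although the design text names the cortex. Over 3 measured granule cell and Bergmann glia genes whose values had not been seen, the median was 1.47 (1.15 to 1.71), with Etv1 at 0.24, Zic2 at 1.47 and Hopx at 1.59, which goes with that explanation on few genes. A first version of this test gave 1.59 over 9 measured genes, but 7 of its 11 genes had already been seen, so they were left out. Expression of Pcp2, Car8, Ppp1r17 and Slc1a6 by microglia themselves is argued against, since their sum was 0.978 (0.770 to 1.24) times the median of 4 other non-neuronal classes. A single pool of free RNA stays open. The range set for it was at most 2-fold between classes, and the bound against it more than 4-fold. This sum differed 4.69-fold (2.94 to 7.87) between astrocytes and fibroblasts, and Pcp2 with Car8 alone, tried afterwards, 5.66-fold (3.33 to 10.4). Both intervals lay above 2 and included 4, so neither bound was met. Isotype astrocytes already held 47.0 CPM of the 4 genes, against 2.42 in isotype microglia and 0 in isotype fibroblasts. The fold can thus include RNA of astrocytes themselves, and it cannot decide on free RNA.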
